A study of Urochloa humidicola with 8 samples.

How the data were processed

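RNA was sequenced from the young leaves of 8 samples of Urochloa humidicola, a tropical forage grass, 4 of them labelled high lignin and 4 low lignin. Per the labels' protocols, the second extended leaf was kept in RNAlater, RNA was extracted with a plant column kit, libraries were made with the TruSeq Stranded mRNA kit and sequencing was done on an Illumina HiSeq instrument. Lignin itself was not measured in the files used here; the group of each sample was taken from its treatment label. Replicate numbers were given in accession order and pair nothing. The labels do not say whether the samples of a group are separate plants, genotypes or repeated leaves, so p-values measure the spread between these samples, part of which may be technical. No batch, sequencing date or growth condition is given in the sources used here.

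The deposited file of each library lists 48695 assembled transcripts with their length, effective length, TPM and estimated count of reads. The submitters' processing notes name FastQC 0.11.8, StringTie 2.0.4 and Salmon 0.7.2 without giving the role of each. The column names per the file headers are those of a Salmon quantification. How the transcript set was assembled, any genome build, the filters used and whether reads were assigned by strand are not given in the sources used here. The estimated counts per the file headers are not normalized and are not all whole numbers. The TPM values deposited by the authors are divided by effective length and sum to the same total in every library, so they keep no depth. The transcripts carry only a running number (asmbl_ and a number) as their name. With no annotation or sequence used here, none could be tied to a gene, and 0 of the IDs matched a gene name. The 14 gene lists fixed before the data were examined, which included the core lignin pathway, lignin polymerisation and markers of other cell types, could therefore not be tested. For the same reason no genomic position is given for any transcript. Values are per transcript and not per gene: reads of alleles, isoforms and near-identical copies in this polyploid grass can be split among entries. Among 40268 transcripts with 10 or more reads in all, 792 shared their length and their estimated reads (to 2 decimals) in every library with at least 1 other transcript.

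The estimated counts were rounded to whole numbers. The comparison of high with low lignin used edgeR 4.0.16 in R 4.3.3: transcripts were kept by filterByExpr with its default limits (27015 of 48695; 4013 had no rounded read in any library), library totals were scaled by TMM, and the quasi-likelihood test was fitted to all 8 libraries with group as the only term. Fold changes are high minus low on the log2 scale. P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05, two-sided. The standard error of a fold change was taken as the fold change over the square root of the F statistic. Libraries were compared by the Spearman correlation of log2 CPM (prior count 2) over the tested transcripts, and the groups by the mean distance (1 minus the correlation) between groups minus that within groups, in an exact one-sided permutation test over the 35 splits of 8 libraries into 4 and 4. The smallest p these splits allow is 0.0286. A transcript was called on in a library at 1 CPM or more and off under 3 reads. CPM, the reads of a transcript scaled to a common library total, was computed from the rounded reads.

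Library totals ran from 7717993 to 10805639 rounded reads, so that 3 reads corresponded to between 0.278 and 0.389 CPM. Reads carried no molecular identifiers, so such limits cover counting error only. The test was tried on simulated counts with the means, dispersions and library sizes of these data, in which 200 of 27015 transcripts were changed. It recovered 0% of them at 2-fold, 0% at 4-fold, 32% at 8-fold and 57.5% at 16-fold. With the dispersion set to 0.02 in place of the fitted one it recovered 200 of 200 at 4-fold, with 11 false calls.

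Transcripts to be named were to be chosen among those past the threshold. As none passed, the 2 with the smallest unadjusted p in each direction are given as examples, chosen after their values were seen. Alternatives were other scaling factors, DESeq2 1.42.0, limma 3.58.1 with voom with and without sample weights, other low-count filters and thresholds, and each library left out in turn. Added after seeing the data were edgeR's robust, legacy and likelihood ratio forms, limma on log2(TPM + 1), other limits and left-out libraries for the on and off calls, read limits for detected transcripts after thinning, and equal group weights for the separation with a library left out. The alternatives for the count at an unadjusted p under 0.05 were also set after seeing the data. Adjusted p-values that DESeq2 gave as missing (12138 of 44682 transcripts) stayed missing.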

Results

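Leaf transcriptomes of Urochloa humidicola were measured in 4 samples chosen for high lignin and 4 chosen for low lignin production, to find transcripts associated with lignin production. The high lignin libraries held 9556635, 9054533, 7717993 and 8766192 rounded reads in replicates 1 to 4, and the low lignin libraries 9049354, 9907147, 10320103 and 10805639. The mean total was 8773840 ± 775979 (SD, n = 4) in high lignin and 10020600 ± 744352 (SD, n = 4) in low lignin, a difference within what relabelling gives (two-sided exact permutation p = 0.0857, 0.238 after Benjamini-Hochberg adjustment over 5 library measures). All values are per assembled transcript, and the transcripts are known here by number only.

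By limits of 1 CPM and 3 reads, the libraries shared part of their transcripts and differed in a large part. Of 37077 transcripts that reached 1 CPM (reads scaled to a common library total) in any library, 17896 (48.3%) reached it in all 8. A further 4654 reached it in 1 library only. In 14982 transcripts (40.4%), at least 1 library was at 1 CPM or more while at least 1 other had fewer than 3 reads. Both limits rest on few reads, since 3 reads corresponded to between 0.278 and 0.389 CPM. How many such transcripts counting noise alone would give was not computed, so these shares are not all differences between leaves. The number of transcripts at 1 CPM or more was 26923 ± 246 (SD, n = 4) in high lignin and 26720 ± 368 (SD, n = 4) in low lignin, which did not differ beyond the replicate spread (two-sided exact permutation p = 0.429, adjusted 0.536). At a limit of 1 or of 10 reads in place of 1 CPM, the high lignin mean lay below the low lignin mean.

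The most abundant transcript in every library was asmbl_291, 3725 bases long. It took 2.68% of all reads on average in high lignin and 4.54% in low lignin, from 1.96% in high lignin replicate 2 to 6.51% in low lignin replicate 1. The groups overlapped (two-sided exact permutation p = 0.114, adjusted 0.238). The 10 most abundant transcripts together took 8.09% of reads in high lignin and 11.7% in low lignin (exact permutation p = 0.143, adjusted 0.238).

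The first comparison asked whether libraries of a group resembled one another more than those of the other group. High lignin replicates 1 and 2 were the closest pair of all 28, with a Spearman correlation across transcripts of 0.897. The 6 pairs within high lignin averaged 0.849, the 6 pairs within low lignin 0.767, and the 16 pairs between groups 0.798. Low lignin replicate 3 stood apart from both groups, with a mean correlation of 0.725 to the other 7 libraries, whereas the other 7 libraries had means between 0.793 and 0.830. The first principal component, with 27.8% of the variance, placed it at 243 and the other 7 libraries between -51.4 and -16.1. Without it, the 3 remaining low lignin pairs averaged 0.819. Distances between groups exceeded those within groups by 0.00939, which 11.4% of the splits reached (one-sided exact permutation p = 0.114). With 1 library left out in the planned form, the value ranged from -0.00855 to 0.0291. It was negative without high lignin replicate 1, 2 or 3. Leaving out 1 library makes the groups unequal. With both groups weighted equally, a form chosen after seeing the data, the value stayed positive whichever library was left out, between 0.00228 and 0.0166 (exact permutation p from 0.0286 to 0.486). No pair of libraries differed as little as sampling noise, the smallest chi-square over its degrees of freedom being 40.1, so none was treated as a repeat deposit of another library.

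**Figure D1:**
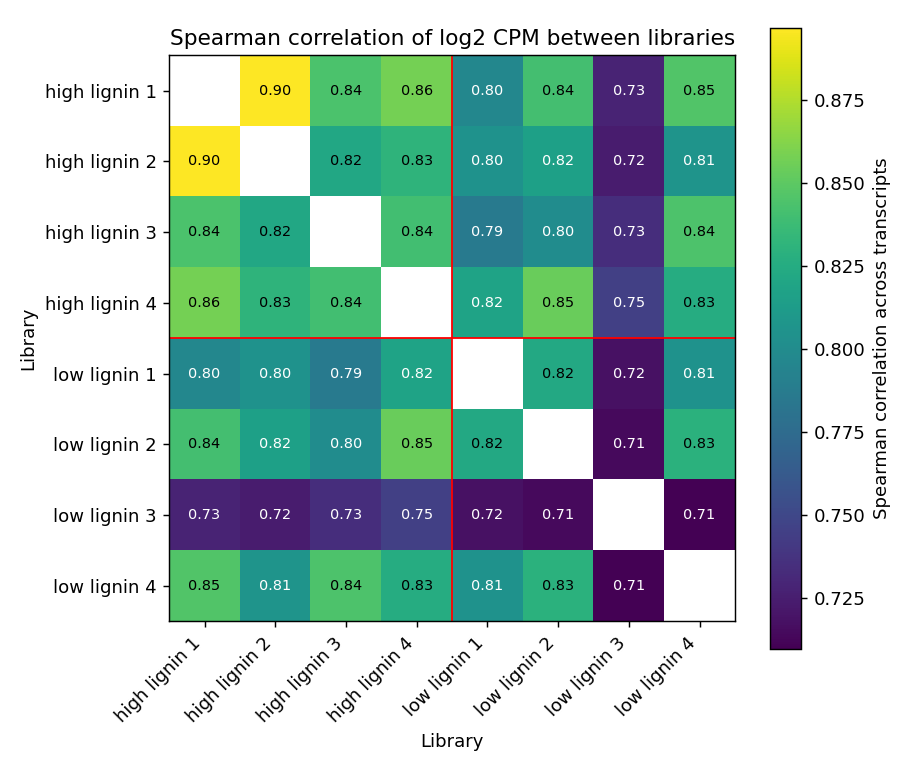
Spearman correlation of log2 CPM across tested transcripts for each pair of the 8 libraries, with group borders in red and the colour scale running from the lowest to the highest pair. Low lignin replicate 3 has the lowest values in its row, with a mean of 0.725, and high lignin replicates 1 and 2 form the closest pair at 0.897.

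Single libraries also differed in which transcripts they held. Low lignin replicate 1 had 592 transcripts at 1 CPM or more that had fewer than 3 reads in each of the other 7 libraries, and these took 0.424% of its reads. Low lignin replicate 3 had 317 such private transcripts with 0.200% of its reads, and low lignin replicates 2 and 4 had 139 and 147. The high lignin libraries had 46, 51, 127 and 124. In the opposite direction, low lignin replicate 3 had fewer than 3 reads for 609 transcripts that reached 1 CPM in each of the other 7 libraries. Low lignin replicate 1 lacked 232 in the same way, and the other 6 libraries lacked between 75 and 127 each.

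**Figure D2:**
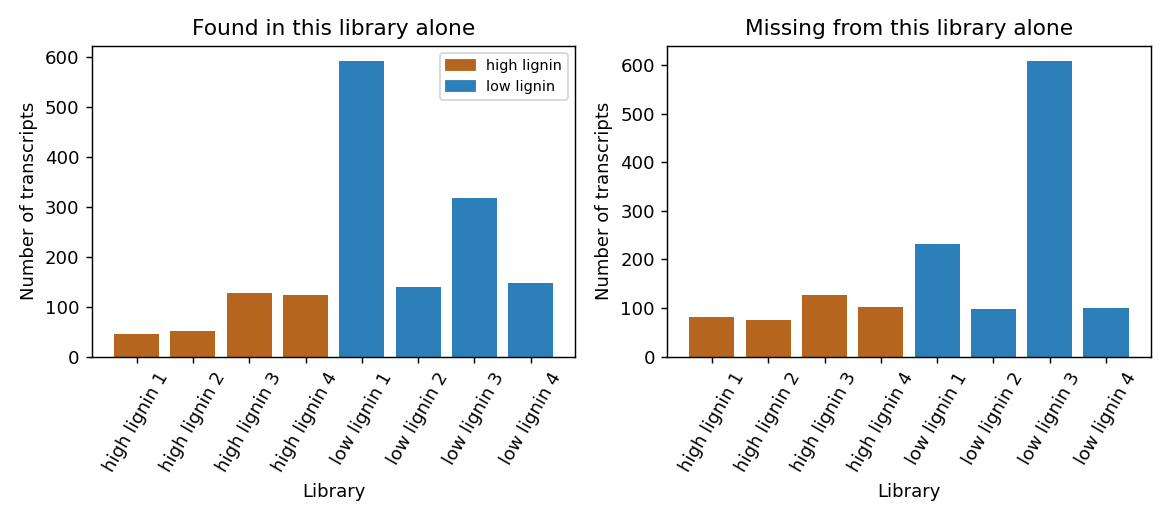
Number of transcripts (vertical axes, from 0) found in 1 library alone at 1 CPM or more (left) and missing from 1 library alone (right), for each of the 8 libraries, coloured by group. Low lignin replicate 1 has the most private transcripts, 592, and low lignin replicate 3 the most missing ones, 609.

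The second comparison asked which transcripts differed between high and low lignin. None of the 27015 transcripts tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test: 0 were higher and 0 lower in high lignin, and the smallest adjusted p was 0.442. At an unadjusted p under 0.05 there were 1581 transcripts, 855 higher and 726 lower in high lignin. If all p-values were uniform, 1351 would be expected. The other splits of these libraries into 4 and 4 gave a median of 1001.5, from 413 to 2066. Of the 35 splits, 3 gave as many as the real one. The variation between samples of a group was large, with a common biological coefficient of variation of 0.698 and a median standard error of 0.53 on the log2 fold change. The median absolute log2 fold change was 0.41. With this spread, simulated changes of 4-fold were not recovered, and 32% of 8-fold and 57.5% of 16-fold changes were. Each simulation planted 200 changes of a single size, so it does not set the limit for the real counts, which may be higher. The real transcript with the smallest unadjusted p was at least 79.2-fold higher in high lignin, and its adjusted p was 0.442. On the same simulated counts DESeq2 recovered 4% of 2-fold and 38% of 4-fold changes among 200, with 102 and 119 false calls. These counts covered only the 27015 transcripts that edgeR tested, so the rates do not describe the wider set DESeq2 had on the real counts. On the real counts DESeq2 called 259 transcripts, 165 higher and 94 lower in high lignin. It was run without edgeR's low-count filter and gave an adjusted p to 32544 transcripts. Of its 259 calls, 171 were among the 27015 transcripts that edgeR tested. The likelihood ratio test of edgeR called 47 (35 higher and 12 lower). Limma on log2(TPM + 1), over 31664 transcripts, called 10, all higher. Limma with voom called 0 (1829 at an unadjusted p under 0.05).

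In 1226 transcripts (4.54%) every high lignin library lay on one side of every low lignin library, against 2.86% by chance for 4 against 4. The other 34 splits of the libraries gave between 375 and 1496 such transcripts, and 3 of the 35 splits gave as many as the real one. Of all transcripts, 15 were on in all 4 high lignin libraries and off in all 4 low lignin libraries, and 5 showed the reverse. Of the 35 splits, 5 gave as many as this total of 20, and the highest other gave 27. The total was 48 at a limit of 0.5 CPM and 6 at 2 CPM. Group accounted on average for 16.9% of a transcript's variance in log2 CPM, where the other 34 splits of the libraries gave between 11.4% and 18.0% (exact permutation p = 0.0857).

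The examples with the smallest unadjusted p show what such differences looked like, although none passed the adjusted threshold in edgeR's quasi-likelihood test. Transcript asmbl_45995, 1977 bases long, had 5.95 CPM ± 1.69 (SD, n = 4) in high lignin, with 208 reads in total, and no read in any low lignin library. Set against 3 reads over the low lignin group it was at least 79.2-fold higher in high lignin. Its adjusted p in edgeR's quasi-likelihood test was 0.442. Transcript asmbl_28296, 291 bases long, had 6.40 CPM ± 1.82 (SD, n = 4) in high lignin, with 228 reads, and none in low lignin, at least 86.8-fold higher. Its adjusted p in edgeR's quasi-likelihood test was also 0.442. In the opposite direction, asmbl_41062, 834 bases long, had no read in high lignin and 11.7 CPM ± 7.77 (SD, n = 4) in low lignin, with 464 reads. It was at least 135-fold lower in high lignin, at an adjusted p of 0.545 in edgeR's quasi-likelihood test. Transcript asmbl_4434, 1596 bases long, was present in all 8 libraries, at 16.7 CPM ± 4.47 (SD, n = 4) in high lignin and 58.7 CPM ± 27.4 (SD, n = 4) in low lignin. Its log2 fold change was -1.79 with a standard error of 0.31 and an adjusted p of 0.564 in edgeR's quasi-likelihood test, and its lowest low lignin library, at 33.9 CPM, lay above its highest high lignin library, at 21.2 CPM. DESeq2 called these 4 transcripts, with adjusted p-values from 3.3e-09 to 0.00033, and edgeR's likelihood ratio test also called all 4, with adjusted p-values from 3.6e-12 to 0.0067. Limma on log2(TPM + 1) called asmbl_28296 (adjusted p = 0.0015) and not the other 3. Over the remaining edgeR and limma alternatives the adjusted p ranged from 0.269 to 0.998.

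**Figure D3:**
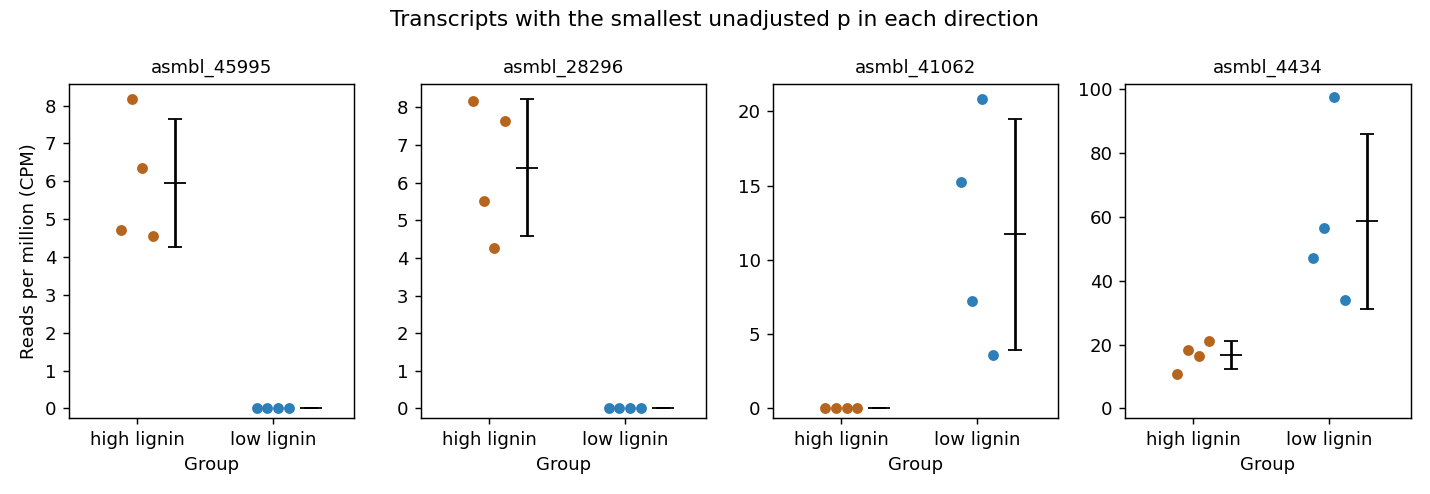
CPM in each library (points) for the 2 transcripts with the smallest unadjusted p in each direction, by group, with the group mean and SD (bars, n = 4). The first pair has no read in low lignin, asmbl_41062 has none in high lignin, and asmbl_4434 is present in all 8 libraries with means of 16.7 and 58.7 CPM.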

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

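One library measure was out of line with the rest of its group. Low lignin replicate 1 had 27266 transcripts at 1 CPM or more, against 26481, 26614 and 26520 in the other low lignin libraries, a gap large enough relative to the range of the group to pass Dixon's criterion at the 95% level. Of 25 such checks 1 passed, and chance alone passes about 5% of them.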

How the results depend on the processing

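Of 20 other fits, 17 gave 0 transcripts at the adjusted threshold. Among these, the legacy form gave the same values as the fit used, and the 8 that left out 1 library (0 to 0; smallest adjusted p between 0.177 and 0.998) have fewer libraries, so their 0 says little about stability. Stricter thresholds give 0 by construction. One exception was DESeq2, run without edgeR's low-count filter, with 259 (165 higher, 94 lower in high lignin). The others, chosen after seeing the data, were the likelihood ratio test with 47 (35 higher, 12 lower) and limma on log2(TPM + 1) with 10 (10 higher, 0 lower). At an unadjusted p under 0.05 the count ranged from 1131 to 3200 over the alternatives (added for this count after seeing the data). The number of transcripts with a p-value differed between them, so the counts are not directly comparable. The 1131 were of 28419 without high lignin replicate 1, and the 3200 of 42815 with DESeq2. Without low lignin replicate 3 the count was 2450 of 28285. The separation of the groups ranged from -0.00855 to 0.0291 when 1 library was left out. It was -0.00855, -0.00839, -0.000766 and 0.00242 without high lignin replicates 1 to 4, and 0.0185, 0.0255, 0.0184 and 0.0291 without low lignin replicates 1 to 4 (exact permutation p = 0.0286 for the last, 0.0571 to 0.743 for the others). This pattern came with the mix of pairs, since low lignin pairs lie further apart: with both groups weighted equally, a form added after seeing the data, the values were 0.00228, 0.00508, 0.0147 and 0.0166 without high lignin replicates 1 to 4 (exact permutation p = 0.0286 for the last) and 0.00316 to 0.0137 without a low lignin library. The high minus low difference in detected transcripts was 203 at 1 CPM, -99.75 at 1 read and -513 at 10 reads; with all libraries thinned to the smallest total it was 178, 164 and 163 at the same limits (the last 2 added after seeing the data), so the reversals came with the unequal totals; it ranged from 123 to 385 with 1 library left out. The count of transcripts on in 1 group and off in the other was 20, 48 at a limit of 0.5 CPM, 6 at 2 CPM, and 30 to 71 with 1 library left out (all added after seeing the data), where fewer libraries have to meet the condition (71 without low lignin replicate 4, 38 without low lignin replicate 3). No paired analysis was possible because the labels give no numbers that pair samples across the groups. The fixed gene lists and their alternatives were not run, since no ID could be matched to a gene.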

Other observations

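The tests in this part were written down before their outcomes were seen, with some exceptions. These were the split count for the edgeR calls at the adjusted threshold, the test of transcript length and the adjustment over the split counts. For private transcripts they were the group tests of private and missing counts and the thinned difference. The private difference without low lignin replicate 1 and the counting error of the gap were exceptions too. The patterns themselves were noticed in these data. Splits divide the same 8 libraries into 4 and 4 in 35 ways, the real one included.

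With edgeR's quasi-likelihood test the real split gave 0 calls and the highest other split 2; all 35 splits give at least 0, so this count decides nothing. At an unadjusted p under 0.05 the real split gave 1581 and the highest other 2066, with 3 of 35 splits as large. For transcripts on in 1 group and off in the other it gave 20 and the highest other 27, with 5 of 35 as large. In the last 2 counts chance cannot be excluded.

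The 259 transcripts called by DESeq2 came with a change of tool and of low-count filter together. Without the filter, edgeR's quasi-likelihood test over 44682 transcripts gave 0 calls, with a smallest adjusted p of 0.668. That argues against the filter alone as the cause. DESeq2 was not run on the real counts with edgeR's filter, so the part of the tool alone was not measured. Of the 259, 171 were among the transcripts that edgeR tested. Other splits gave a median of 108 DESeq2 calls and up to 459, and 4 of 35 splits gave as many as the real one, so chance cannot be excluded. In simulated counts for this comparison with 200 transcripts changed 8-fold, DESeq2 recovered 69.5% and made 112 false calls, against 32% and 5 for edgeR's quasi-likelihood test. The simulation covered only the 27015 transcripts that edgeR tested, a smaller set than DESeq2 had on the real counts. A whole group near 0 accounts for only part of the list: 34.7% of the 259 had fewer than 3 reads in every library of 1 group. For limma on log2(TPM + 1), the real split gave 10 calls and the highest other split 9, a lead of 1 call that gives the smallest share the splits allow (1 of 35), with a tool added after seeing the data. Adjusted over the 4 split counts that could decide, the share is 0.114, so chance cannot be excluded there either. Of the 10, 8 were also called by DESeq2. The 10 include asmbl_28296 and transcripts with adjacent numbers, which may come from 1 locus, so they may not be 10 separate differences.

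Low lignin replicate 3 stood apart from the other 7 libraries. The values argue against depth as the cause: with all libraries thinned to the smallest total its mean correlation was 0.724 and the lowest other library stood at 0.792. A transcript length bias is argued against, since length explained 0.240% of the variance of its deviation from the mean profile, within the 0.0542% to 0.487% of the other 7 libraries; other effects of RNA quality were not tested. Added reads from another source are argued against as the whole cause: without private transcripts, over all transcripts with a read, its mean correlation was 0.768 against 0.807 for the next library (0.763 against 0.790 over the same set with private transcripts kept, a smaller gap than in the tested transcripts), and added reads would not remove the 609 transcripts it alone lacked (next highest 232). A different genotype, ploidy, leaf stage or a mislabelled sample stay open and were not tested, since the labels describe none of them.

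Each low lignin library held more private transcripts than any high lignin library, 299 ± 212 (SD, n = 4) against 87.0 ± 44.5 (SD, n = 4), higher in 4 of 4 libraries (two-sided exact permutation p = 0.0286, the smallest possible, and 0.0571 after adjustment over 2 measures; missing transcripts gave p = 0.229). Depth is argued against as the whole cause. With all libraries thinned to the smallest total the means were still 341 in low and 104 in high lignin (exact permutation p = 0.0286). The means then lay 237 apart, against 212 before. Thinning raised the mean of both groups, so this widening is not evidence in itself. After thinning, the lowest low lignin count exceeded the highest high lignin count by only 6, less than the counting error of that gap (17.4). With low lignin replicate 1 left out of the means, the difference fell from 212 to 114, and from 237 to 133 after thinning. The exact permutation p was 0.0286 for both, the smallest possible. Leaving out the highest library could not undo the order of the groups, so this p adds no support. The counts of the remaining libraries were not remade and still refer to all 8 libraries. A closer resemblance among the high lignin libraries stays open: counted against the 4 libraries of the other group alone the order stayed (572 ± 286 in low and 290 ± 15.3 in high lignin, exact permutation p = 0.0286), but resemblance within a group would give the same order, so the count does not decide.

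Other hypotheses gave mixed results. The mean distance within low lignin was 0.233 and within high lignin 0.151 (exact permutation p = 0.0571), but without low lignin replicate 3 the difference was 0.0295 (exact permutation p = 0.286), so greater variety of the group was not shown. Transcripts whose numbers differ by 1 moved together more than random pairs: the median correlation across libraries was 0.138 over 15958 pairs, against at most 0.00949 in 100 random pairings, and 4.19% of the pairs had a correlation over 0.9, against at most 0.395% (a share compared after it was seen). This is consistent with some neighbouring numbers marking transcripts of 1 locus, in which case counts of transcripts overstate the number of genes behind them.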
